A study of Drosophila melanogaster with 4 samples.

How the data were processed

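Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on wild-type Oregon-R embryos of Drosophila melanogaster at 14 to 16 h of development, with an antibody labelled MOF Q4145. Per the labels, the series holds 4 libraries: 2 ChIP replicates and 2 input libraries, 1 input for each ChIP replicate. Per the labels' protocols, embryos were crosslinked with formaldehyde and the crosslinked chromatin was incubated with antibody before DNA was recovered. The labels do not say whether the replicates came from separate embryo collections, so the spread between them may be technical. The sample titles do not give the sex of the embryos, so the share of males in the chromatin is unknown. Read counts of the ChIP and input libraries were not analysed here.

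The authors deposited 3 lists of regions of significant enrichment, termed clusters below: 1 list per ChIP replicate and 1 list for the set of both replicates. Per the file headers, coordinates are on FlyBase release 5 (genome build r5) and count from 1. The submitters' processing notes name Bowtie 0.12.7. The peak caller, its threshold and the way in which the replicates were combined are not given in the sources used here. Each cluster carries a start, an end and a score. The authors deposited these scores without a stated scale, and they were read here as log2 values of an enrichment ratio, scaled by 1 constant per list, because of the values themselves. After subtraction of the commonest score of a list, 2 to the power of the score was a ratio of whole numbers, with a denominator of at most 1000 and a relative tolerance of 1e-10, for 99.8% of clusters in replicate 1, 99.8% in replicate 2 and 98.4% in the replicate set. The same test gave 0.794%, 0.384% and 0.61% with powers of e, and 0% in each list with base 2 after a small arbitrary shift of the scores. Since each list carries its own scaling constant, scores were compared within a list, and scores of the same cluster in different lists are given side by side as values of separately scaled lists. The numerator is taken to be ChIP and the denominator input, as the labels pair them. The depth of the libraries is unknown, so no counting error of a score can be given.

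Chromosome lengths were taken from the file headers. X was compared with the 4 large autosome arms 2L, 2R, 3L and 3R, and chromosome 4, the heterochromatic scaffolds and the unplaced scaffolds were kept apart. The covered share and the number of clusters (by midpoint) were summed in 1 Mb windows, 23 on X and 99 on the autosome arms. The log of the X to autosome ratio, averaged over both replicates, was tested by a two-sided permutation test of the windows between X and autosomes with 100000 resamples. Differences in median score and median width were tested by a two-sided permutation test of the clusters, also with 100000 resamples. For the mean of both replicates this test relabelled the 2 lists independently, although most of their clusters overlap. Its p for the mean is therefore likely too small. Windows and clusters are not replicates: with 2 ChIP libraries, these tests describe the distribution along the genome and not the variation between embryos. As neighbouring windows resemble each other, the X block was also rotated along the concatenated arms over all 122 positions. Positions near the true one still contain part of X, so this comparison is coarse and partly made of X itself. Overlap between lists required 1 shared base and was set against 1000 circular shifts of one list along each chromosome. Shares of clusters carry exact (Clopper-Pearson) 95% intervals, which cover counting error only.

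The tests were checked on simulated lists of 3800 clusters, 20 per setting. The simulated clusters were placed independently, so they lack the grouping of real ones. Each simulated test used 1 list, so p values for the mean of both replicates were not checked in this way. A true X to autosome density ratio of 1.1 was recovered as 1.11 ± 0.0526 (SD) and passed the threshold of 0.05 in 14 of 20 simulations, a ratio of 1.5 passed in 20 of 20, and a ratio of 1 passed in 2 of 20. A score difference of 0.08 was recovered as 0.068 ± 0.024 (SD) and passed in 15 of 20 simulations, and a difference of 0 in 1 of 20. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0.

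The comparisons, the alternatives and the rule for named clusters were fixed before the data were examined, except where a choice is said to have been made afterwards. The rule named the 10 highest-scoring clusters on X and the 10 on the autosome arms of the replicate-set list, among those that overlap a cluster in both replicates, and the highest-scoring cluster on each other scaffold. Alternatives were the clusters at or above the median score of each list, merging of neighbours within 500 bp, inclusion of chromosome 4 and heterochromatin, windows of 250 kb, a reciprocal overlap of 50 percent, and each list alone. The available gene table is on genome release 6, so its coordinates were not combined with the release 5 clusters. The 6 planned comparisons that need a release 5 annotation or sequence (start site share, gene body share, position within genes, genes with a cluster, gene lists and GA repeat content) were therefore not analysed here, and clusters are named by coordinates.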

Results

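MOF is a histone acetyltransferase that acetylates histone H4. In Drosophila it is a subunit of the dosage compensation (MSL) complex, which acts on the single X chromosome of males, and of the NSL complex, which is found at genes on all chromosomes. Its occupancy was profiled in Oregon-R embryos at 14 to 16 h in 2 ChIP libraries, each with its own input. The data consisted of 4158 enriched clusters in replicate 1, 3911 in replicate 2 and 6232 in a list for the replicate set. The clusters covered 9.69 Mb, 9.15 Mb and 13.7 Mb of the release 5 genome. Median cluster widths were 2093, 2097 and 2030 bp. Median scores corresponded to 1.67-fold, 1.86-fold and 1.43-fold enrichment over input in the authors' scaling. The 5 large arms held 97.5% of the clusters of replicate 1, 97.5% of those of replicate 2 and 95.3% of those of the replicate set.

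The first comparison concerned the distribution of MOF over X and autosomes. Clusters occurred on all large arms, and X was the most densely covered of the 5 arms in both replicates and in the replicate set. Clusters covered 8.88% ± 0.264 (SD, n = 2) of X and 7.48% ± 0.329 (SD, n = 2) of the 4 autosome arms together. Among autosome arms, 2R was closest to X with 8.16% ± 0.241 (SD, n = 2), followed by 3R with 7.76% ± 0.409 and 3L with 7.37% ± 0.397, and 2L was lowest with 6.62% ± 0.237. Coverage of X exceeded that of 2R by a ratio of 1.09 in each replicate, and that of 2L by 1.34 and 1.35. The X to autosome ratio of covered share was 1.18 in replicate 1 (permutation p = 0.0301), 1.20 in replicate 2 (permutation p = 0.0148) and 1.23 in the replicate set (permutation p = 0.00275). Its mean over both replicates was 1.19 ± 0.0169 (SD, n = 2), and the permutation test of windows gave p = 0.0205. When X was moved as 1 block along the arms, an alternative chosen after the data were seen, the two-sided exact p was 0.164, and with 5 arms no ranking of arms can give a p below 0.2.

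**Figure D1:**
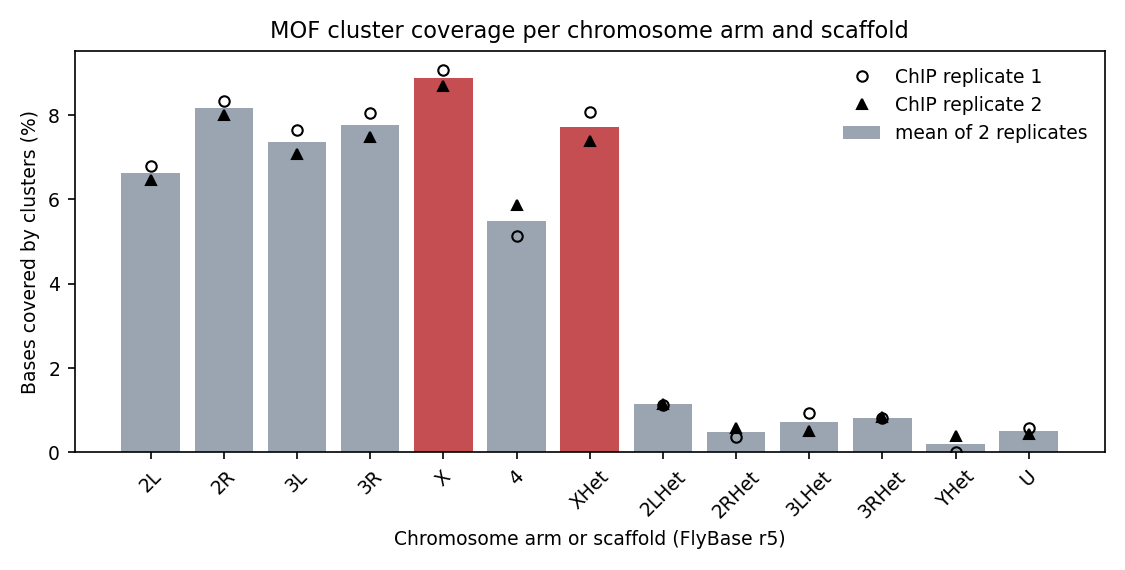
Share of bases covered by MOF clusters (percent, y axis) on each chromosome arm or scaffold of release 5 (x axis); bars give the mean of 2 ChIP replicates, circles replicate 1 and triangles replicate 2, with X and XHet in red. X had the highest mean of the 5 large arms, 8.88%, and the heterochromatic scaffolds other than XHet, with the unplaced scaffold U, lay at or below 1.14%.

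By number, X carried 36.8 ± 0.662 clusters per Mb (SD, n = 2) and the autosome arms 32.2 ± 1.58. The ratio was 1.14 ± 0.0356 (SD, n = 2), and the permutation p of 0.05 lay at the threshold (0.0500195 before rounding). Replicate 1 alone gave a density ratio of 1.12 (permutation p = 0.108) and replicate 2 alone 1.17 (permutation p = 0.0235). Mean cluster width was 2436 bp on X and 2315 bp on autosomes in replicate 1, and 2396 and 2333 bp in replicate 2. Median widths did not separate the chromosomes: they differed by 12 bp in replicate 1 and by -16.5 bp in replicate 2, X minus autosomes (permutation p = 0.804 for the mean of both).

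Clusters of at least 3 kb were denser on X than on autosomes. This split by width was chosen after the data were seen. Clusters of at least 3 kb made up 18.3% of X clusters (153 clusters, 95% interval 15.8 to 21.1%) and 14.6% of autosomal clusters (470 clusters, 13.4 to 15.9%) in replicate 1, with a Fisher's exact p of 0.00969. In replicate 2 the shares were 17.1% (139 clusters) and 14.7% (440 clusters), with a Fisher's exact p of 0.0983, and the replicate set gave 17.1% and 14.6% (Fisher's exact p = 0.0281). Clusters of at least 5 kb made up 3.71% on X and 2.02% on autosomes in replicate 1 (Fisher's exact p = 0.00685), 3.32% and 2.07% in replicate 2 (0.0483) and 3.35% and 2.13% in the replicate set (0.0132). The density of clusters of at least 3 kb on X relative to autosomes was 1.38 ± 0.0293 (SD, n = 2; permutation p = 0.016), and 1.97 ± 0.126 (permutation p = 0.0287) for clusters of at least 5 kb. Clusters under 3 kb had a ratio of 1.103 ± 0.0466 (SD, n = 2; permutation p = 0.15), and of 1.15 in the replicate set (permutation p = 0.0147). Whether the ratios of wide and narrow clusters differ was not tested beyond the Fisher's exact tests of the shares. Those tests were not adjusted for their number and treated neighbouring clusters as independent. They drew on 3 lists from the same 2 ChIP libraries, so a width effect apart from the general excess on X is weakly supported. Of the 5 widest clusters of the replicate set, 4 lay on X. These were 7583860 to 7594738 (10879 bp), 3666292 to 3676162 (9871 bp), 12553498 to 12563124 (9627 bp) and 3578065 to 3587624 (9560 bp). The largest overlapping clusters of replicates 1 and 2 spanned 10006 and 10008 bp, 7219 and 7185 bp, 9420 and 6820 bp, and 9554 and 9425 bp in the same order. The widest of all, at 2191532 to 2204562 on 2L, spanned 13031 bp in the replicate set, 5146 bp in replicate 1 and 5080 bp in replicate 2. With X moved as 1 block, the exact p for clusters of at least 3 kb was 0.139.

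Coverage varied along X as well as between arms. The most densely covered 1 Mb windows of X were 1 to 2 Mb (12.9% ± 1.35, SD, n = 2), 6 to 7 Mb (12.5% ± 0.322) and 3 to 4 Mb (11.2% ± 0.269). The lowest full windows were 21 to 22 Mb (3.94% ± 0.547), 20 to 21 Mb (4.90% ± 0.0158) and 14 to 15 Mb (4.92% ± 0.619). On autosomes the densest window was 5 to 6 Mb of 3R, with 13.6% ± 0.72 (SD, n = 2). In the replicate set this window was covered to 18.5% and the window of X at 1 to 2 Mb to 19.2%. It was followed by 17 to 18 Mb of 3L, with 12.5% ± 0.115. The lowest full autosomal windows were the first Mb of 2R (0.779% ± 0.0661) and 23 to 24 Mb of 3L (0.825% ± 0.145). The median full window was covered to 9.18% on X (22 windows) and to 7.48% on autosomes (95 windows), and 17 of the 22 X windows lay above the autosomal median. These windows were singled out after their values were seen.

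**Figure D2:**
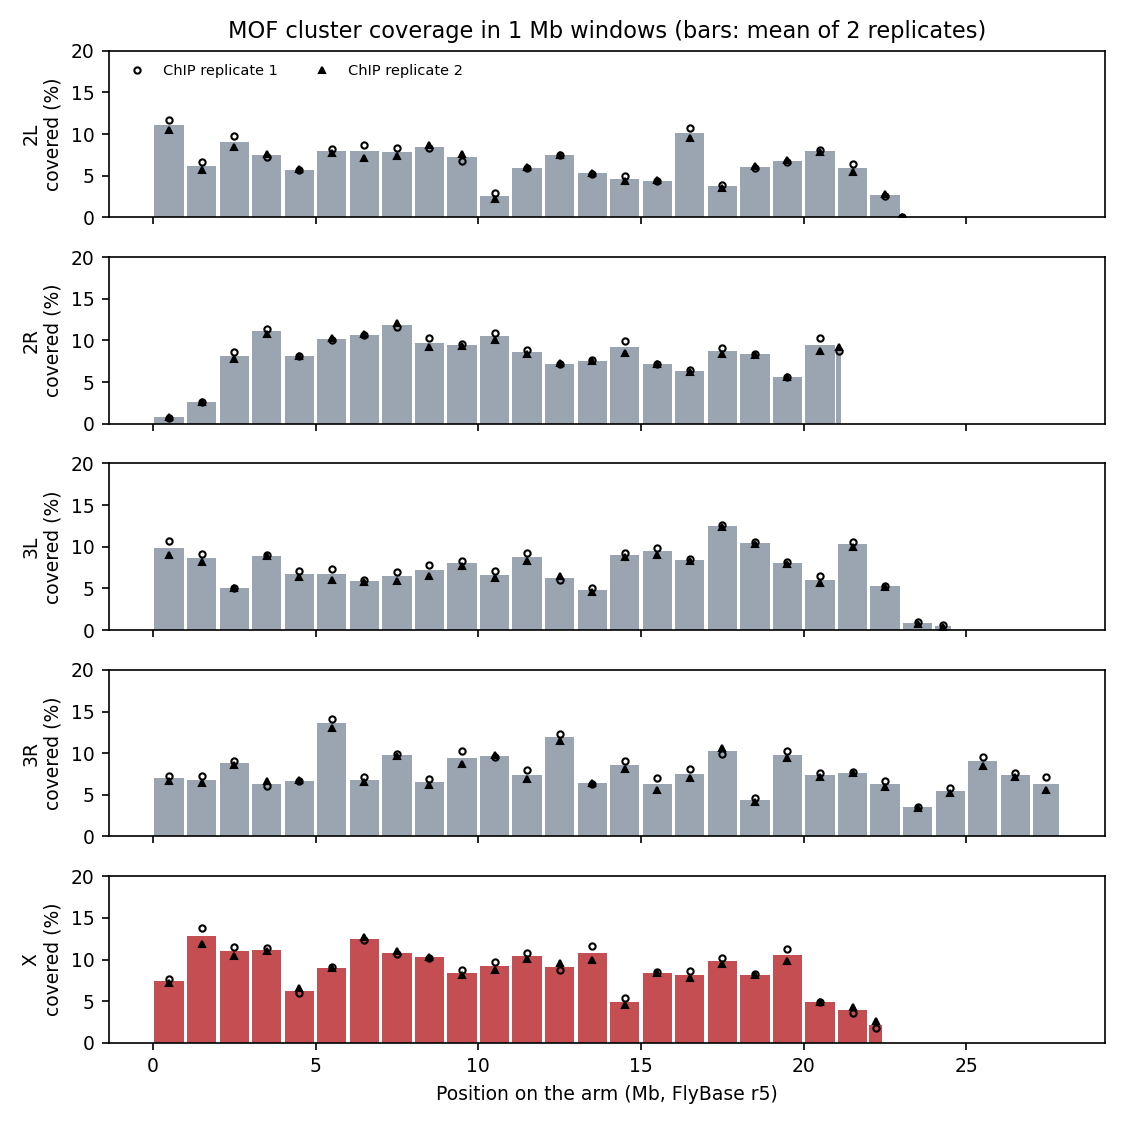
Share of bases covered by MOF clusters (percent, y axis) in consecutive 1 Mb windows along the 5 large arms (x axis, position in Mb, release 5); bars give the mean of 2 ChIP replicates, circles replicate 1 and triangles replicate 2. On X (red) the full windows range from 3.94% at 21 to 22 Mb to 12.9% at 1 to 2 Mb, and single autosomal windows such as 5 to 6 Mb of 3R reach 13.6%.

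The second comparison concerned the strength of enrichment. Scores were slightly higher on X than on autosomes. The median score on X was 0.80 in replicate 1 against 0.72 on autosomes (permutation p = 0.00167), and 0.94 against 0.89 in replicate 2 (permutation p = 0.117). The mean difference was 0.063 ± 0.019 on the log2 scale (SD, n = 2), a 1.04-fold higher ratio. Its permutation p of 0.00178 treated the 2 overlapping lists as independent and so overstates the evidence. Resampling 1 Mb windows as blocks, an alternative chosen after the data were seen, gave a 95% interval of 0.028 to 0.11. Here too the windows were drawn separately for each replicate. For each replicate alone, the block interval at the median was 0.034 to 0.14 in replicate 1 and -0.0090 to 0.12 in replicate 2, which includes 0.

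The X chromosome was poor in weakly enriched clusters. When each list was split into score quartiles over the 5 arms, the lowest quartile had an X to autosome density ratio of 0.641 ± 0.0803 (SD, n = 2), the second 1.49 ± 0.0848, the third 1.30 ± 0.00585 and the highest 1.23 ± 0.0252. Over the 12 tests, adjusted by Benjamini-Hochberg, the lowest quartile lay below 1 in replicate 1 (adjusted permutation p = 6.0e-05), in replicate 2 (adjusted permutation p = 0.0011) and in the replicate set (adjusted permutation p = 0.00012). The middle quartiles lay above 1 in all 3 lists, with adjusted permutation p values of at most 0.0151. As the quartiles divide each list, a shortage on X in the lowest one raises the ratios of the others. The whole lists already had ratios of 1.12, 1.17 and 1.19, against which the quartiles were not tested. The ratios above 1 are therefore no separate result, and the 3 lists rest on the same 2 ChIP libraries. The highest quartile did not pass the adjusted threshold in any list (adjusted permutation p = 0.0546, 0.108 and 0.0546). This split was chosen after the data were seen.

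**Figure D3:**
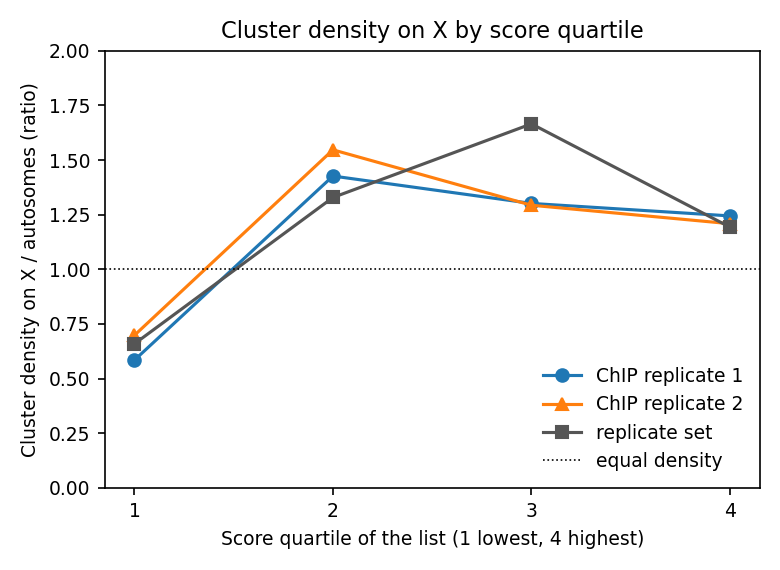
Ratio of cluster density on X to that on the 4 autosome arms (y axis) in each score quartile of a list (x axis, 1 lowest and 4 highest), for each ChIP replicate and the replicate set; the dotted line marks equal density. The lowest quartile lies below 1 in all 3 lists (0.584, 0.698 and 0.659), and the other quartiles lie above 1.

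The strongest clusters lay on autosomes as well as on X. Among clusters found in both replicates, the highest on autosomes was at 8292481 to 8295120 on 3R, with a score of 3.65 in the replicate set (12.5-fold), 3.43 in replicate 1 and 3.96 in replicate 2. Another 2 of the 10 named autosomal clusters lay close to it on 3R, at 8302206 to 8304458 (score 3.42) and at 8333595 to 8335798 (score 2.89). A wide cluster of 7494 bp at 14746957 to 14754450 on 3L reached 3.43 in the replicate set, 3.28 in replicate 1 and 3.59 in replicate 2. On 2L the cluster at 22017819 to 22020345 had a score of 3.19, and on 2R that at 19552985 to 19555668 had 3.05. The other 4 named autosomal clusters, 2 on 2R and 1 each on 2L and 3L, scored between 2.97 and 3.02. On X the highest were 2210483 to 2212853, with 3.28 in the replicate set (9.72-fold), 3.24 in replicate 1 and 3.29 in replicate 2, and 16109834 to 16112699, with 3.27, 3.09 and 3.38 in the same order. These were followed by 19575994 to 19578623 (2.96), 1976740 to 1979092 (2.87) and 7595616 to 7597920 (2.67), the last of which lay beside the 10879 bp cluster on X. The remaining 5 X clusters, at 11899927, 11579238, 1868894, 7192798 and 18205676 (start positions), scored between 2.49 and 2.66. The 10 named clusters thus spanned 5.63-fold to 9.72-fold on X and 7.43-fold to 12.5-fold on autosomes. The 4 autosome arms together (96.6 Mb) offer a larger pool than X (22.4 Mb). The lists carry separate scaling constants, so these values are set side by side without an error.

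The third comparison concerned the agreement of the replicates. Of the clusters of replicate 1, 81.2% (3378 of 4158; 95% interval 80.0 to 82.4%) shared at least 1 base with a cluster of replicate 2. The reverse share was 86.7% (3391 of 3911; 85.6 to 87.8%). Circular shifts of replicate 2 gave 14.2% ± 0.82 (SD of the shifts) and 15.1% ± 0.87, and no shift reached the observed values (permutation p = 0.001, the smallest that 1000 shifts can give). The replicates shared 7.93 Mb of 10.9 Mb covered in either, a Jaccard index of 0.726. Over the 3378 overlapping pairs the scores had a Pearson r of 0.927 and a Spearman rho of 0.882 across clusters, which are not independent replicates.

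**Figure D4:**
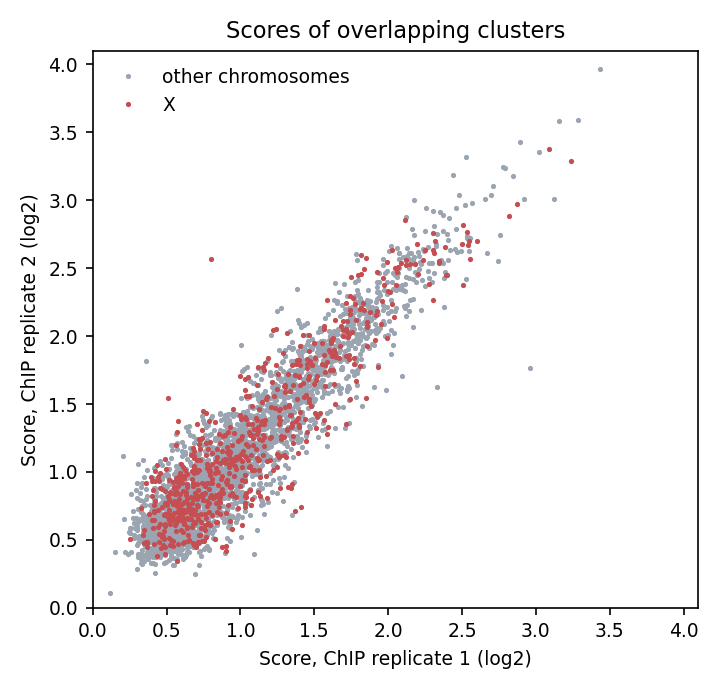
Score of each replicate 1 cluster (x axis, log2) against that of the replicate 2 cluster with which it shares most bases (y axis, log2), for 3378 pairs, with clusters on X in red. The 2 lists carry separate scaling constants, so the axes are not on a common scale. Scores rise together (Pearson r 0.927).

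Clusters that failed to recur were weaker and narrower than those that did. Their median score was 0.51 against 0.87 for recurring clusters in replicate 1, and 0.59 against 1.00 in replicate 2, with median widths of 1619 against 2154 bp and 1590 against 2139 bp. In replicate 1, 56.5% of the lowest score quartile recurred and 99.1% of the highest. X and autosomal clusters of replicate 1 recurred in 81.3% and 81.8% of cases (Fisher's exact p = 0.764). In replicate 2, fewer X clusters recurred, 83.8% (81.1 to 86.3%) against 88.0% (86.8 to 89.1%) on autosomes, with a Fisher's exact p of 0.00177. Over bases covered in both replicates, an alternative chosen after the data were seen, the X to autosome ratio was 1.17, with a permutation p of 0.0497 that lay at the threshold. Clusters of the replicate set that overlapped both replicates had an X to autosome density ratio of 1.101, against 1.15 for those overlapping replicate 1 alone, 1.63 for replicate 2 alone and 1.27 for neither, values that were not tested against each other.

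The list for the replicate set contained nearly all clusters of the single replicates, 98.9% of replicate 1 and 99.0% of replicate 2. In turn, 53.5% of its clusters (3335 of 6232; 52.3 to 54.8%) overlapped clusters of both replicates, 11.6% (723) of replicate 1 alone and 7.61% (474) of replicate 2 alone. The other 27.3% (1700 clusters; 26.2 to 28.4%) overlapped neither. Those 1700 had a median width of 1277 bp and a median score of 0.40, against 2295 bp and 0.88 for clusters found in both. Of the 1700, 898 were narrower than 1301 bp, the smallest width in either replicate list, while the replicate set began at 1001 bp.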

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

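These clusters lie outside the 5 arms compared and were picked out because more than 3 were called in each replicate. Whether they differ from the input was decided by the authors' threshold, and no control track was analysed here. Chromosome 4, the small and largely heterochromatic autosome, had 33 clusters in replicate 1 and 38 in replicate 2, or 26.3 ± 2.62 per Mb (SD, n = 2). That was below the 32.2 ± 1.58 per Mb of the large autosome arms, and 28 of them recurred in either direction. With 33 and 38 clusters the counting error is wide, and the difference in density was not tested. Its highest-scoring cluster, at 1315424 to 1317737, scored 1.94 in the replicate set, 1.98 in replicate 1 and 2.00 in replicate 2. The heterochromatic scaffolds of the autosomes (2LHet, 2RHet, 3LHet and 3RHet) had 33 clusters in replicate 1 and 31 in replicate 2, 3.67 ± 0.162 per Mb, of which 19 recurred.

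XHet, a scaffold of 0.204 Mb, had 8 clusters in replicate 1 and 8 in replicate 2, of which 7 recurred. This is 39.2 per Mb, above the other heterochromatic scaffolds, against 36.8 ± 0.662 per Mb on X. With only 8 clusters the counting error is wide, so likeness to X cannot be judged. The unplaced scaffold U had 32 clusters in replicate 1 and 18 in replicate 2, of which 15 and 14 recurred.

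The highest-scoring clusters of several of these scaffolds in the replicate set had no counterpart in a replicate. The one on U at 7619239 to 7620399, with a score of 3.99, that on 3RHet at 1034260 to 1035267 (3.46), that on 2RHet at 1843750 to 1844766 (1.95) and that on 2LHet at 29333 to 30400 (0.93) overlapped neither replicate. That on 3LHet at 1238090 to 1240958 scored 2.96 in replicate 1 and 1.77 in replicate 2. That on XHet at 113131 to 115332 scored 1.16 and 1.18. That on YHet, at 108216 to 109347, overlapped replicate 2 alone, with a score of 1.78 there.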

How the results depend on the processing

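The X to autosome ratio of covered share stayed above 1 under every alternative run. It kept its side of the threshold except when X was rotated as 1 block (1.19, exact p = 0.164), which also ended the call for clusters of at least 3 kb (1.38, exact p = 0.139). Both alternatives were chosen after the data were seen. They keep neighbouring windows together, but they also use only 122 positions, of which those near the true one still contain part of X. Their higher p values can therefore not be put down to the likeness of neighbouring windows alone. The density ratio lay at the threshold. It passed among clusters at or above the median score (1.26) and with chromosome 4 and heterochromatin included (1.24). Windows of 250 kb (1.14) and the replicate-set list (1.19) passed as well. It ranged from 1.12 without replicate 2 to 1.17 without replicate 1, which passed. The score cut favours X, which held few of the lowest-scoring clusters. Autosomal heterochromatin was sparse in clusters (3.67 ± 0.162 per Mb), which raises the ratio. Windows of 250 kb leave the ratio unchanged and only add correlated units. The replicate-set list rests on the same 2 ChIP libraries. Its clusters overlapping both replicates had a density ratio of 1.101, below those overlapping replicate 1 alone (1.15), replicate 2 alone (1.63) or neither (1.27). Passes under these score, scaffold, window and replicate-set settings, for density and covered share, are weak support. The density ratio did not pass after merging (1.13, permutation p = 0.0563). In alternatives chosen after the data were seen, it did not pass over clusters that overlap the other replicate (1.11, permutation p = 0.148) or with X rotated as 1 block (exact p = 0.197). The score difference ranged from 0.050 to 0.077 with 1 replicate left out, losing significance without replicate 1. Its value of -0.015 among clusters at or above the median score decides nothing, since the clusters were selected by the score that is compared. The width difference, -2.25 bp over both replicates and not significant under any alternative, was 11.25 bp among clusters at or above the median score, 7.5 bp after merging, and ranged from -16.5 to 12 bp with 1 replicate left out. The share of replicate-set clusters found in both replicates was 55.6% at or above the median score and 52.2% with a reciprocal overlap of 50 percent, against 53.5%. The cause was not tested for these changes. Of 45 alternatives, 31 were unchanged, 5 came to pass the threshold, 3 no longer passed it, 4 changed sign and 2 moved. Unchanged meant the same direction and side of the threshold. The share of replicate-set clusters found in both replicates has neither, so its values were held against its main interval (52.3 to 54.8%). It stayed inside only after merging (54.3%). The overlap of the replicates stayed at the smallest permutation p that its shifts can give, so its unchanged results say little. No paired analysis was possible because no processed file of the input libraries was used, and the ChIP replicates are the only group with values. The 6 comparisons that need a release 5 annotation or sequence were not run. Depth is unknown, so weak clusters cannot be given a counting error.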

Other observations

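MOF clusters lay nearer to each other than random placement gave, on X and on autosomes, in a test chosen after the data were seen. In replicate 1 the median gap between neighbouring clusters was 11.9 kb on X, against 16.9 ± 0.614 kb (SD of 1000 draws) when the same clusters were placed at random, and 14.3 kb on autosomes, against 19.1 ± 0.354 kb. In replicate 2 the gaps were 11.7 kb on X (17.4 ± 0.635 kb at random) and 16.5 kb on autosomes (20.6 ± 0.395 kb). Each permutation p was 0.001, the smallest that 1000 draws can give. Gaps under 5 kb made up 31.4% on X and 25.2% on autosomes in replicate 1, where random placement gave 18.6% and 16.6%. Random placement did not keep the variation of coverage along the arms, which can shorten median gaps without any local grouping. Local grouping of clusters was therefore not separated from it. A difference in grouping between X and autosomes was not tested. Coverage of the 117 full 1 Mb windows had a Pearson r of 0.971 and a Spearman rho of 0.968 between replicates, across windows that are not independent, in a comparison also chosen after the data were seen.

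The following tests bear on patterns already seen, and those of recurring coverage and of scaffolds were chosen after their result was known, as were the block rotation and the percentiles other than the 10th and 90th. The higher coverage of X was set against 3 technical explanations. A few dense windows were argued against, since without the top decile of windows of X and of the autosomes by coverage the ratio was 1.19 (permutation p = 0.0191). Cluster-poor ends of the autosome arms were argued against too: without 3 Mb at both ends of each arm the ratio was 1.18 (permutation p = 0.0231). Over bases covered in both replicates the ratio was 1.17, against 1.19 over all covered bases. The size of the excess thus changed little without calls that do not recur. Whether the remaining excess passes was not decided, because its permutation p of 0.0497 had a resampling error (0.0484 to 0.0511) that includes the threshold. The density ratio over clusters that overlap the other replicate was 1.11 (permutation p = 0.148), against 1.14 over all clusters. The block rotation (1.19, exact p = 0.164) leaves chance differences between arms open. A difference in copy number or mappability of X was not tested, and the share of males, on which the copy number of X depends, is unknown. No biological explanation was tested, as the design has no group that lacks dosage compensation. The ratio of X to autosomes is therefore not a measure of the male X alone.

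The shortage of weak clusters on X may come from 1 offset of all X scores or from a higher calling floor on X. The X minus autosome difference at the 10th percentile was 0.072 in replicate 1 (block bootstrap interval 0.052 to 0.095) and 0.073 in replicate 2 (0.037 to 0.10). At the 90th percentile it was 0.071 (-0.075 to 0.18) and 0.075 (-0.096 to 0.24). The mean difference between both percentiles was -0.00041. At the 75th percentile the X minus autosome difference was 0.095 in replicate 1, 0.023 in replicate 2 and 0.0010 in the replicate set. The 10th less the 75th percentile was -0.023 (-0.11 to 0.088), 0.050 (-0.13 to 0.16) and 0.047 (-0.037 to 0.12), so neither equal nor unequal shifts are excluded. In the replicate set the shift at the 10th percentile was smaller than at the 25th by 0.011, with an interval (-0.0194 to -0.000598) that excluded 0, without adjustment for the number of intervals. With an interval half-width of up to 0.173, larger than the offset itself, a floor cannot be told apart from an offset.

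The clusters of the replicate set that overlap neither replicate may rest on few reads. Since a score is log2 of a ratio of whole numbers, exactly recurring scores are expected when those numbers are small. Within score deciles, these clusters had an exactly recurring score more often by 33.7 percentage points than clusters found in both replicates (41.1% against 7.80% without matching; permutation p = 1e-04, the smallest that 10000 draws can give). Repeat-rich scaffolds as the main origin were argued against, as they held 8.94% of these clusters (exact 95% interval 7.63 to 10.4%). That share exceeded the 1.20% of clusters found in both replicates, 3.87% of those overlapping replicate 1 alone and 2.95% for replicate 2 alone, so the scaffolds are open as the origin of a small part. Repeats within the large arms were not tested. The smaller minimum width of the replicate-set list leaves a different calling setting open.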
